A study of Mus musculus with 6 samples.

How the data were processed

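Small RNA libraries of cultured mouse spermatogonial stem cells came from 6 samples, 1 per group. Per the labels, the cells were taken from an F1 male of C57BL/6 and DBA2 with an actin-EGFP transgene and grown on mouse embryonic fibroblast feeders. They were transfected with Cas9 and guide RNAs against mHen1 or Mili, and single colonies were picked and checked by Sanger sequencing. Total RNA was used with or without NaIO4, and the sixth library came from RNA bound to MILI by a commercial antibody. Spike-ins were added to 5 libraries per the labels. Their sequences are not given in the sources used here and none were identified, so no absolute amounts were derived.

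The values of each file are counts of reads per distinct sequence, made by the authors before the files were deposited by collapsing identical reads. No header was present, the values were whole numbers, and the totals differed between files, so no scaling had been applied. Bowtie (no version given) and build mm10 are named per the submitters' processing notes. The adapter sequence, its trimming and the length filter are not given in the sources used here. Sequences were 17 to 40 nt long, with 41 nt in the immunoprecipitate. Distinct sequences numbered 1183331 in untreated wild type, 1906319 in wild type with NaIO4, 2736244 in the untreated Hen1 knockout, 420795 in the Hen1 knockout with NaIO4, 290499 in the Mili knockout and 7617386 in the immunoprecipitate. Those seen in 1 read made up 32.8%, 28.3%, 40.9%, 45.8%, 33.6% and 58.8% of them. Sequences of 18 to 35 nt were kept, which held 92.6%, 95.6%, 95.3%, 91.9%, 90.5% and 96.0% of the reads. At these depths a share of the library had a 95% interval of under 0.1 points to each side, while sequences with few reads had wide ones.

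Sequences were matched to the transcripts of GENCODE M21 (GRCm38) with bwa 0.7.19-r1273 (aln and samse, no gaps, up to 3000 places each, all places within the mismatch limit kept). No genome sequence was in the reference, so classes were set from transcripts, which departs from the design's genome matching, and introns and unannotated regions were not read. Small RNA classes were given by exact sense matches to annotated small RNAs plus 16 tRNA and 2 rRNA sequences written by hand, in the order microRNA, tRNA, rRNA, mitochondrial rRNA and tRNA, snRNA and snoRNA, other small RNA. Transcripts that hold rRNA (Gm42418, Gm26917, CT010467.1 and AY036118) were counted as rRNA. piRNA-like meant 25 to 31 nt with none of these classes, and the MILI-bound set was the piRNA-like sequences with at least 10 reads in the immunoprecipitate, 210864 in number. Nuclear tRNAs other than the 16 written by hand were not in the reference. Fragments of tRNA variants can therefore count as piRNA-like and as MILI-bound. piRNA-like reads were divided by exact matches to longer transcripts, sense or antisense. Any sense match made a read sense, in the order protein-coding gene, long non-coding RNA, pseudogene. Antisense thus held only reads without a sense match to any of these transcripts. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pyarrow 21.0.0, edit distances with edlib 1.3.9.post1 and figures with matplotlib 3.10.9.

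The planned comparisons were NaIO4 against none in wild type and in the Hen1 knockout, the ratio of these ratios, each knockout against untreated wild type, and the immunoprecipitate against untreated wild type. All were ratios of shares with intervals from the read counts. No test was made, since each group had 1 library. The sequence rule counted piRNA-like sequences with at least 10 reads in both untreated libraries and a NaIO4 ratio of at least 2. For 3′ ends, reads that share their first 20 nt with MILI-bound reads were compared. Tails were up to 3 bases at the 3′ end that the source transcript does not hold. They were read at 5′ ends where at least 1 whole read matched 1 gene in the sense. Whether the first 20 nt alone also lie in other genes was not checked, so reads from other copies can count as tailed. Reads that departed from the transcript earlier were left out. Overlaps of 5′ ends were counted on the longest transcript of each gene, from 1 to 20 nt, and the z-score set 10 nt against the other overlaps. microRNAs were counted by hairpin gene and side of the hairpin, since mature arms were not in the reference. Their ratios used reads scaled to all microRNA reads with 0.5 added to each count, for arms with at least 200 reads in both libraries together.

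Lists of microRNAs were fixed before the data were examined, as were the size windows, the read limits, the fold rules and the rule for named items. They were the let-7 family, the miR-17 and miR-106b clusters, the miR-290 and miR-302 clusters, undifferentiated spermatogonia, meiotic and later germ cells, fibroblasts (the feeders), blood, endothelium, muscle, and mirtrons with other microRNAs made without Drosha. Each list median was set against 10000 random lists of the same size drawn from the 40 microRNAs nearest in level to each member. The draws were independent, while the fixed lists hold arms of the same hairpin, cluster or family, which may move together. The percentiles can therefore overstate how unusual a list was. Members not in the reference or without reads were Mir18a, Mir302a, Mir302b, Mir302c, Mir302d, Mir367, Mir449b and Mir486b. Named microRNAs were the 8 with the highest and the 8 with the lowest ratios of each comparison plus the 2 to 4 most abundant members of each list. Named piRNAs were the 5 most abundant in the immunoprecipitate and the 5 with most reads among those at least 2-fold higher with NaIO4 in wild type and not in the knockout. Named structural RNA fragments were the 3 most abundant of each class in wild type with NaIO4, and the text gives part of them. Of the source genes with the most reads in the immunoprecipitate, 1 is not reported.

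Chosen after the data were seen were the Mir5099-locus class, the hand-written tRNA and rRNA sequences, the source gene rule, the search for SINE B1 and B2 (consensus sequences written by hand) with up to 4 edits among sequences with at least 100 reads, and the tRNA fragment table. The division of microRNA entries by name, the counts per Mir5099-locus read and per transcript-matched read, the counts per microRNA read other than for the ratio of ratios, up to 1 mismatch for the piRNA-like ratios, and the read limits and length groups of the 3′ end comparison were also chosen then. The alternatives planned in advance were another size window, leaving out sequences of fewer than 2 reads or the 10 most abundant sequences, counting distinct sequences once, up to 1 mismatch for class shares, other limits of the MILI-bound set, other scalings, and other read limits.

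The calls were tested on simulated data. For the sequence rule, 200 sequences were given an 8-fold higher share in wild type with NaIO4, and 154 of the 160 that met the read limits were found. Among sequences left as they were but drawn at random around equal shares, 0.467% passed in wild type and 3.05% in the knockout. For microRNAs, 37 of 37 measured arms given a 4-fold difference were found, and 5 others passed. Of 751 reads given tails, 751 were called and 0 others. That result was fixed by construction, since the reads were cut from the transcript and each added base differed from it. It gives no rate of false tails among real reads. For overlaps, 502 pairs were found where 500 had been added, against a mean of 1.58 at other overlaps. Of 100 sequences given adapter-like bases 100 were found, with 15 of 1000 random ones. Finding the added pairs and the adapter-like sequences was likewise fixed by construction. Only the values at other overlaps and for random sequences could have come out otherwise.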

Results

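Small RNAs were sequenced from cultured mouse spermatogonial stem cells, the self-renewing germ cells of the testis, grown on embryonic fibroblast feeders. The series asked which small RNAs these cells make in wild type cells and in cells without Hen1 or Mili, and which of them carry a modified 3′ end. Hen1 (gene Henmt1) is the methyltransferase that adds a 2′-O-methyl group to the 3′ end of piRNAs, and MILI (gene Piwil2) is a Piwi protein that binds piRNAs, the small RNAs that silence transposons in the germ line. There were 6 libraries and 1 library per group. They were untreated wild type (7905850 reads), wild type with NaIO4 (10752278), untreated Hen1 knockout (12284947), Hen1 knockout with NaIO4 (2833286), untreated Mili knockout (5310972) and a MILI immunoprecipitate from wild type cells (26292082). NaIO4 oxidises RNAs whose last ribose has free 2′ and 3′ hydroxyls, which then do not enter the library, while 2′-O-methylated RNAs resist. Shares were taken of the reads of 18 to 35 nt, which numbered 7322408, 10282416, 11702714, 2604390, 4808088 and 25240941 in that order.

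With 1 library per group no difference had a replicate check, so every comparison is between these libraries and not between conditions, and no p-value is given. Intervals are 95% exact (Clopper-Pearson) for shares and from the read counts on the log scale for ratios. They cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Both knockouts were compared with the same untreated wild type library, so part of any likeness between them may come from it.

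Reads from the targeted genes were few in every library. Henmt1 gave 21 small RNA reads in untreated wild type, 16 with NaIO4, 88 in the untreated Hen1 knockout, 8 with NaIO4, 0 in the Mili knockout and 117 in the immunoprecipitate. Piwil2 gave 289, 863, 677, 68, 2 and 2609 in that order. Reads of 18 to 35 nt from an mRNA are not a measure of that mRNA, so these counts do not check the genotypes.

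Reads of piRNA size, 25 to 31 nt, made up 46.5% (46.4 to 46.5) of the wild type library, with the most common length among them at 28 nt. That share was 69.5% (69.5 to 69.6) with NaIO4, 75.2% (75.2 to 75.2) in the MILI immunoprecipitate and 19.2% (19.2 to 19.2) in the Mili knockout. In the Hen1 knockout it was 62.0% (62.0 to 62.0) without NaIO4 and 31.1% (31.1 to 31.2) with it, and the most common length was 27 nt in both libraries. Reads of microRNA size, 20 to 24 nt, made up 39.4%, 20.99%, 26.1%, 57.3%, 64.0% and 13.2% of wild type, wild type with NaIO4, Hen1 knockout, Hen1 knockout with NaIO4, Mili knockout and immunoprecipitate. Among reads of 25 to 31 nt, the share that began with T (U in the RNA, the usual first base of piRNAs) was 68.9% (68.8 to 68.9) in wild type, 84.9% (84.9 to 85.0) in the immunoprecipitate and 28.8% (28.7 to 28.9) in the Mili knockout. It was 78.8% in wild type with NaIO4 and 75.4% and 53.7% in the Hen1 knockout without and with NaIO4. An A at position 10, the mark of piRNAs made by reciprocal cleavage, stood in 27.9% of wild type reads of that size, 28.9% with NaIO4, 28.5% and 25.1% in the Hen1 knockout without and with NaIO4, 19.0% in the Mili knockout and 28.1% in the immunoprecipitate. At 20 to 24 nt an A at position 10 stood in 15.8% of wild type and 14.3% of Mili knockout reads.

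**Figure D1:**
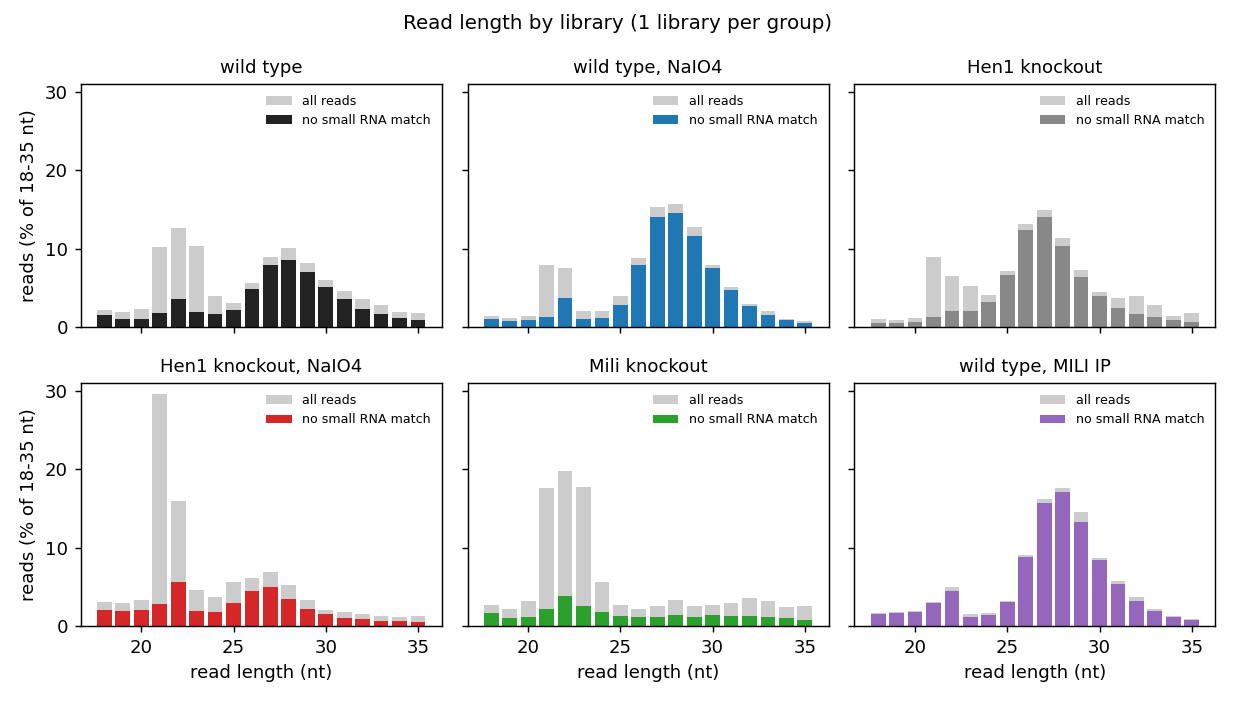
Share of reads (% of reads of 18 to 35 nt) at each length in nt, 1 panel per library; grey bars show all reads and darker or coloured bars those with no match to a known small RNA class. The most common length among reads of 25 to 31 nt was 28 nt in untreated wild type and 27 nt in the Hen1 knockout, and reads of 25 to 31 nt made up 19.2% of the Mili knockout library.

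Classes were set by exact matches to annotated small RNAs, and reads of 25 to 31 nt in none of these classes were called piRNA-like. piRNA-like reads held 39.2% (39.2 to 39.2) of the wild type library, and 22.8% of the library was piRNA-like and in the sense of a protein-coding gene. Another 13.9% was piRNA-like with no match to a transcript, and reads with antisense matches alone were 0.807%. Reads with matches of both kinds, such as those of repeats, counted as sense. With transcript-matched piRNA-like reads spread over all their places on the longest transcript of each gene, 10.8% lay antisense. microRNAs held 19.2% (19.2 to 19.2), tRNA fragments 4.21%, rRNA fragments 3.79%, snRNA and snoRNA fragments 3.60% and mitochondrial RNA fragments 2.98%. A single short RNA with the sequence annotated as Mir5099 took 7.80% (7.78 to 7.82) and was kept as its own class after its share was seen.

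**Figure D2:**
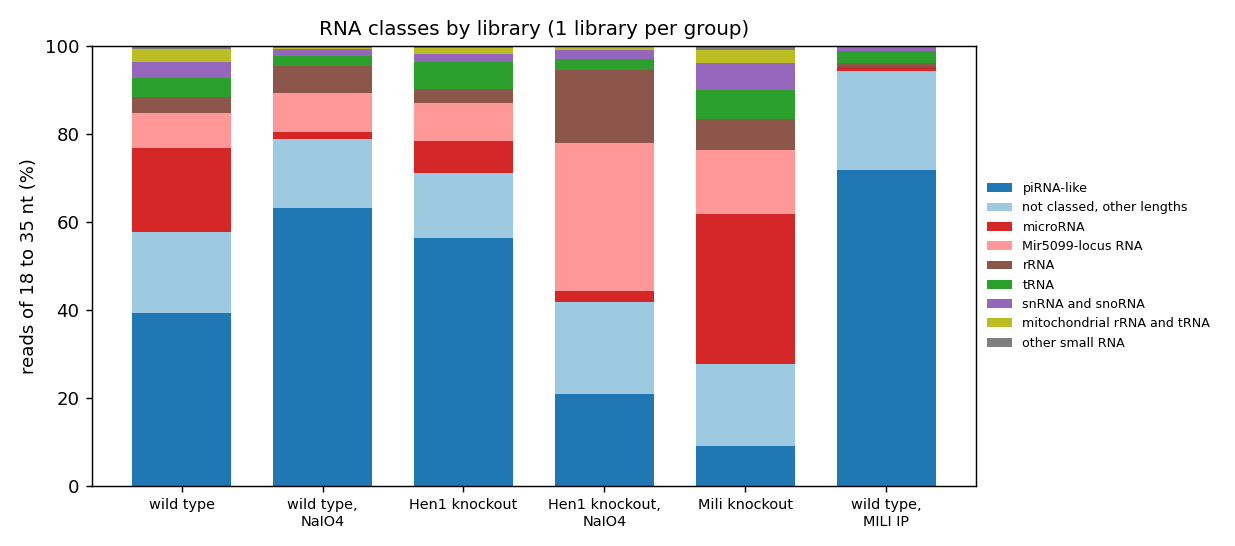
Share of reads of 18 to 35 nt (%) in each RNA class, as stacked bars for the 6 libraries. piRNA-like reads held 39.2% of untreated wild type, 63.2% with NaIO4, 56.4% and 20.8% of the Hen1 knockout without and with NaIO4, 9.07% of the Mili knockout and 71.8% of the MILI immunoprecipitate.

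In wild type cells, microRNAs were depleted with NaIO4 and piRNAs were kept. The piRNA-like share was 1.61-fold higher with NaIO4 (1.61 to 1.61), at 63.2% against 39.2%, while the microRNA share was 13.0-fold lower (12.9 to 13.0), at 1.48% against 19.2%. Per microRNA read the piRNA-like ratio was 20.9. Within piRNA-like reads, those in the sense of protein-coding genes were 1.81-fold higher (1.81 to 1.81), those from long non-coding RNAs 1.70-fold higher (1.69 to 1.71) and antisense reads 1.58-fold higher (1.56 to 1.59). The MILI-bound set, 210864 piRNA-like sequences with at least 10 reads in the immunoprecipitate, was 1.55-fold higher (1.55 to 1.55). Mitochondrial fragments were 8.54-fold lower (8.44 to 8.64), snRNA and snoRNA fragments 2.55-fold lower (2.53 to 2.56) and tRNA fragments 1.75-fold lower (1.74 to 1.76). rRNA fragments were 1.63-fold higher (1.62 to 1.64) and Mir5099-locus reads 1.14-fold higher (1.14 to 1.14). The rRNA value rested largely on 5S fragments that end in GACCGCC, which held 4.81% with NaIO4 against 6.18% for all rRNA fragments. Of 1104 rRNA sequences with at least 10 reads in both untreated libraries, 83 were at least 2-fold higher and 423 at least 2-fold lower. Their median ratio was 0.654. Shares add up to the whole, so a higher share of 1 class can come from the loss of another.

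In the Hen1 knockout piRNA-like reads were depleted with NaIO4 along with microRNAs. Their share was 2.71-fold lower with NaIO4 (2.70 to 2.72), at 20.8% against 56.4%, beside 2.85-fold lower (2.83 to 2.88) for microRNAs, 2.59-fold lower (2.57 to 2.61) for tRNA fragments and 1.69-fold lower (1.67 to 1.71) for mitochondrial fragments. The MILI-bound set was 3.04-fold lower (3.02 to 3.06) and piRNA-like reads in the sense of protein-coding genes 3.42-fold lower (3.41 to 3.44). Higher shares were found for rRNA fragments, 5.48-fold (5.45 to 5.50), Mir5099-locus reads, 3.87-fold (3.86 to 3.88), unclassed reads of other lengths, 1.43-fold (1.42 to 1.43), and snRNA and snoRNA fragments, 1.19-fold (1.18 to 1.20). The 5S fragments that end in GACCGCC held 14.0% of this library, against 16.6% for all rRNA fragments. Of the same 1104 rRNA sequences, 522 were at least 2-fold higher and 277 at least 2-fold lower, with a median ratio of 1.75. Because the Mir5099 locus alone took 33.5% of this library, the size of the piRNA-like difference depended on the total. The piRNA-like ratio of 0.369 (0.368 to 0.370) was 1.05 per microRNA read, so that piRNA-like reads and microRNAs were depleted about alike, 0.0953 per Mir5099-locus read, 0.557 without the 10 most abundant sequences of each library and 0.718 with each distinct sequence counted once.

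Set against wild type, the NaIO4 ratio of piRNA-like reads in the Hen1 knockout was 4.37-fold lower (4.36 to 4.38), that of the MILI-bound set 4.71-fold lower (4.68 to 4.74) and that of piRNA-like reads in the sense of protein-coding genes 6.20-fold lower (6.17 to 6.23). The ratio of ratios of piRNA-like reads was 0.229 in the main scaling, 0.0504 per microRNA read, 0.0674 per Mir5099-locus read, 0.148 of transcript-matched reads, 0.358 without the 10 most abundant sequences and 0.624 with distinct sequences counted once. Sequence by sequence, 15118 piRNA-like sequences had at least 10 reads in both untreated libraries. By the rule of size, 3221 of them were at least 2-fold higher with NaIO4 in wild type and 449 in the knockout, with 64 in both. Simulated libraries drawn around equal shares gave 0.467% in wild type and 3.05% in the knockout, against 2.97% observed in the knockout. Most knockout sequences lay far below equal shares, so that rate cannot tell whether the 449 exceed counting error. With at least 50 reads, 5.57% were higher in the knockout. At least 2-fold lower were 2846 in wild type and 12016 in the knockout, and the ratio was lower in the knockout for 84.7% of the sequences. The median ratio was 1.27 in wild type and 0.180 in the knockout. The knockout value rests on few reads per sequence, since its NaIO4 library held 2604390 reads against 11702714 untreated. With at least 50 reads in both untreated libraries the medians were 1.39 and 0.267. Per microRNA read the higher and lower counts were 13691 and 756 in wild type and 2032 and 7461 in the knockout, and per Mir5099-locus read 2126 and 3217 in wild type and 57 and 14661 in the knockout. With a 4-fold rule the counts of higher sequences were 223 and 188, and with at least 50 reads 307 and 97 of 1743.

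Individual piRNA source genes followed the same course. Among the 12 genes with the most 1-gene reads in the immunoprecipitate were D10Wsu102e (chromosome 10, 83360221 to 83488505), Fth1 (chromosome 19, 9980598 to 9985098), which encodes the ferritin heavy chain, and Cbx5 (chromosome 15, 103191544 to 103239816), which encodes the heterochromatin protein HP1 alpha. The list also held Abl2, a tyrosine kinase (chromosome 1, 156558786 to 156649568), Trim71, a ubiquitin ligase and let-7 target (chromosome 9, 114507133 to 114564369), Eif4ebp2, a repressor of translation initiation, Tmem245, Rab11fip4, Gabpb2, Fbxo41 and Cbl. Coordinates are of GRCm38 with the GENCODE M21 annotation. With NaIO4, D10Wsu102e reads were 1.77-fold higher in wild type (1.75 to 1.80) and 3.63-fold lower in the knockout (3.52 to 3.75). The same pair of values was 1.73 (1.68 to 1.78) and 4.41-fold lower (4.12 to 4.72) for Fth1, 1.94 (1.90 to 1.99) and 3.45-fold lower (3.29 to 3.61) for Abl2, and 1.94 (1.88 to 2.00) and 3.61-fold lower (3.37 to 3.86) for Cbx5. Of 1215 genes with at least 200 piRNA-like reads in wild type, a rule added after the data were seen, 1204 were higher with NaIO4 in wild type, with a median ratio of 1.88. Of the 1197 of these with at least 200 reads in the untreated Hen1 knockout as well, 1195 were lower with NaIO4 in the knockout, with a median ratio of 0.279.

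The most abundant piRNAs of the immunoprecipitate came from SINE B2 repeats and from histone H3 genes. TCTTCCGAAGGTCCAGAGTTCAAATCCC, with 7322 rpm (reads scaled to the library total) in the immunoprecipitate, lay within 4 edits of the sense strand of B2 and matched transcripts of 89 genes, among them the last exon of a 6-exon Fn1 transcript on the minus strand of chromosome 1 (71644584 to 71644611). Its share was 1.71-fold higher with NaIO4 in wild type (1.67 to 1.74) and 3.42-fold lower in the Hen1 knockout (3.14 to 3.71). Shifted or shorter forms of it were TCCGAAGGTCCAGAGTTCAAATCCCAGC at 4367 rpm, which matched 86 genes including Raph1 (chromosome 1, 60513935 to 60513962), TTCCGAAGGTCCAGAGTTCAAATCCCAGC at 2393 and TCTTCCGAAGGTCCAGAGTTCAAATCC at 2200. TTCAAGACCGACCTGCGCTTCCAGAGC, at 2744 rpm, matched the coding sequence of 10 genes including the histone H3 gene Hist1h3h (chromosome 13, 21717893 to 21717919). This sequence was 1.57-fold higher with NaIO4 in wild type (1.48 to 1.67) and 3.55-fold lower in the knockout (2.62 to 4.79). Which of the matched copies gave such reads could not be decided from their sequence.

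The 5 piRNA-like sequences with the most reads among those at least 2-fold higher with NaIO4 in wild type and not in the knockout included 4 within 1 or 2 edits of a tRNA. GTTTCCGTAGTGTAGTGGTCATCACGCTC, 2 edits from tRNA-Val-AAC, was 2.02-fold higher in wild type (1.91 to 2.13) and 5.28-fold lower in the knockout (4.76 to 5.86). TCCCATGGTCTAGCGGTTAGGATTCCT, 2 edits from tRNA-Glu-TTC, was 2.75-fold higher (2.59 to 2.92) and 3.16-fold lower (2.35 to 4.27), and GTTTCTGTAGTGTAGTGGTTATCACGCT had NaIO4 ratios of 2.15 and 0.325. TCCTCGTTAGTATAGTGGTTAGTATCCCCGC, 1 edit from tRNA-Asp-GTC, had ratios of 2.07 (1.91 to 2.24) and 0.317 (0.232 to 0.432). The remaining sequence, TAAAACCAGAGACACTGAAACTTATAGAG, matched 67 genes including an untranslated region of the vomeronasal receptor gene Vmn1r26 (chromosome 6, 58006840 to 58006868), with ratios of 2.11 (1.95 to 2.28) and 0.422 (0.296 to 0.604). The 4 tRNA-like sequences had 2510 to 9007 reads in the immunoprecipitate and so were in the MILI-bound set. They were at 0.0380 to 0.630 of untreated wild type in the Mili knockout and may be tRNA fragments.

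Some fragments of structural RNAs also had higher shares with NaIO4, and part of them did so in the Hen1 knockout. Single fragments were named for their reads in wild type with NaIO4, which favours high wild type ratios. They do not stand for their classes, and mitochondrial fragments as a class were 8.54-fold lower in wild type. The 5S group below was set after the data were seen. Fragments of 5S rRNA that end in GACCGCC held 0.669% of untreated wild type and 4.81% with NaIO4, 7.20-fold higher (7.13 to 7.26). In the Hen1 knockout they held 0.315% and 14.0%, 44.5-fold higher (44.0 to 45.0). The most abundant ones were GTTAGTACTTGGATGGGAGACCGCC, 4.52-fold higher in wild type (4.44 to 4.60) and 29.2-fold in the knockout (28.6 to 29.9), AGTACTTGGATGGGAGACCGCC, 6.10-fold and 41.2-fold, and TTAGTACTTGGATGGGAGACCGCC, 6.27-fold and 40.6-fold. The mitochondrial 12S rRNA (mt-Rnr1) fragment AAGGTGTAGCCAATGAAA was 3.47-fold (3.10 to 3.88) and 22.8-fold (20.0 to 25.9) higher, and the Mir5099-locus RNA TCTTAGATCGATGTGGTGCTC 1.15-fold (1.15 to 1.16) and 3.83-fold (3.81 to 3.84) higher. A fragment of the snoRNA Gm26202 had ratios of 1.12 (1.08 to 1.17) and 3.68 (3.45 to 3.93), and a Snord42a fragment 0.756 (0.727 to 0.786) and 2.80 (2.66 to 2.95). By contrast, the 5′ fragment TCCCACATGGTCTAGCGGTTAGGATTCCT of tRNA-Glu-TTC was 2.50-fold higher in wild type (2.44 to 2.57) and at a ratio of 0.358 in the knockout (0.315 to 0.407). A tRNA-Glu variant fragment had ratios of 2.94 (2.85 to 3.04) and 0.322 (0.274 to 0.378), a 33-nt tRNA-Val-AAC 5′ fragment 1.20 (1.17 to 1.22) and 0.192 (0.180 to 0.206), and the signal recognition particle RNA fragments of Gm23153 and Rn7s1 1.29 and 1.47 in wild type and 0.104 (0.0330 to 0.326) and 0.349 (0.162 to 0.754) in the knockout.

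Without NaIO4, Hen1 knockout cells kept piRNA-like reads, and these reads had shorter and more often extended 3′ ends. The piRNA-like share was 1.44-fold higher than in wild type (1.44 to 1.44), or 3.76-fold per microRNA read, the MILI-bound set 1.08-fold higher (1.08 to 1.08), or 0.972 per Mir5099-locus read, and piRNA-like reads with no transcript match 1.72-fold higher (1.72 to 1.73). The microRNA share was 2.61-fold lower (2.60 to 2.62), snRNA and snoRNA fragments 2.11-fold lower (2.10 to 2.13), mitochondrial fragments 2.10-fold lower (2.08 to 2.11) and rRNA fragments at 0.802 of wild type (0.798 to 0.806), while tRNA fragments were 1.497-fold higher (1.491 to 1.504). The MILI-bound set consists of exact sequences from wild type cells, so a read with a shortened 3′ end leaves it. Transcript matches were exact as well, so a read with added 3′ bases can fall among those with no transcript match.

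3′ ends were compared within 5′ ends, as reads that share their first 20 nt with MILI-bound reads. Over 3854 such 5′ ends with at least 50 reads in both untreated libraries, the mean read length was lower in the Hen1 knockout for 3256, or 84.5%, with a median difference of -0.72 nt (quartiles -1.37 and -0.22). For comparison, wild type with NaIO4 against untreated wild type gave a median of -0.03 nt over 4303 5′ ends, and the immunoprecipitate -0.10 nt over 4354. The difference was larger where piRNAs were longer, with 5′ ends grouped by their mean length in the immunoprecipitate, which enters neither side of the difference. The medians were -0.38 nt at 773 5′ ends under 27 nt, -0.89 nt at 908 of 28 to 29 nt and -1.11 nt at 446 of 30 nt or more. Over 134725 5′ ends, reads of 26 and 27 nt made up 23.8% in wild type and 37.9% in the knockout, and reads of 28 to 35 nt 57.5% and 42.9%. Tails were read at 96574 5′ ends with a read that matched 1 gene. Of all reads there, 13.6% in wild type, 11.8% in the Hen1 knockout and 26.1% in the Mili knockout departed earlier and were left out. Among the rest, bases that the source transcript does not hold ended 11.4% (11.4 to 11.5) of wild type reads and 21.2% (21.2 to 21.3) of Hen1 knockout reads. Tails made of T alone (U in the RNA) were found on 3.40% (3.36 to 3.44) and 8.28% (8.24 to 8.32), and tails of A alone on 1.01% and 4.37%. The wild type with NaIO4 had 2.94% T tails, the immunoprecipitate 2.53% and the Hen1 knockout with NaIO4 6.97%. In the Mili knockout, with 6675 such reads, tails of any base stood on 19.2% (18.2 to 20.1) and T tails on 3.61% (3.18 to 4.09), so a high share of tails of any base was not particular to the Hen1 knockout. microRNAs, which Hen1 does not methylate in mammals, had a median length difference of 0.01 nt over 348 5′ ends and T tails on 4.23% of wild type and 4.59% of knockout reads.

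**Figure D3:**
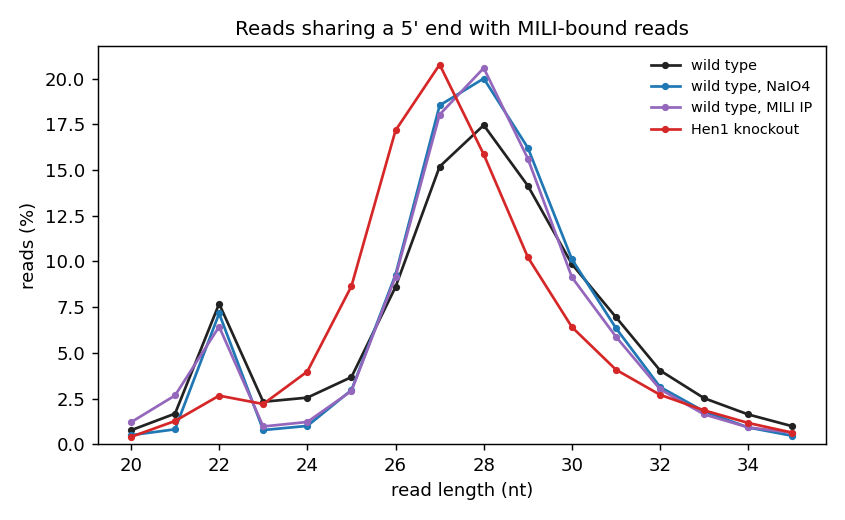
Lengths of reads that share their first 20 nt with MILI-bound reads, as % of such reads at each length in nt, in untreated wild type, wild type with NaIO4, the MILI immunoprecipitate and the untreated Hen1 knockout. In the Hen1 knockout the lengths lay lower, with 37.9% of reads at 26 and 27 nt against 23.8% in untreated wild type.

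In the Mili knockout nearly all piRNAs that come from genes were missing. The piRNA-like share was 4.32-fold lower than in wild type (4.31 to 4.34), at 9.07% against 39.2%. Among them, reads in the sense of protein-coding genes were 29.96-fold lower (29.7 to 30.3), those from pseudogenes 34.9-fold (30.7 to 39.8), those from long non-coding RNAs 22.4-fold (21.6 to 23.2) and antisense reads 8.64-fold lower (8.38 to 8.91). piRNA-like reads with no transcript match were 1.71-fold lower (1.70 to 1.72), and 31.4% of all piRNA-like reads left began with T against 75.7% in wild type. The piRNA-like reads left can include fragments of tRNA variants absent from the reference, so they are not all piRNAs. The microRNA share was 1.77-fold higher (1.77 to 1.78), that of rRNA fragments 1.88-fold, of snRNA and snoRNA fragments 1.69-fold, of tRNA fragments 1.57-fold and of Mir5099-locus reads 1.86-fold higher. Per Mir5099-locus read, microRNAs were at 0.955 of wild type and piRNA-like reads at 0.125, per microRNA read piRNA-like reads were at 0.131, and of transcript-matched reads alone piRNA-like reads were at 0.0358. With distinct sequences counted once the piRNA-like ratio was 0.415 in place of 0.231.

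At the level of genes, 1201 of the 1215 source genes were at least 2-fold lower in the Mili knockout and 1184 at least 10-fold, with a median of 336-fold. D10Wsu102e had 34 reads against 27371 in wild type, 529-fold lower (378 to 740), and Fth1 30 against 6605, 145-fold lower (101 to 207). Cbx5 had 10 reads against 6041, 397-fold lower (213 to 738), and Abl2 1 read against 9931, with a ratio of 1.53e-04 (2.16e-05 to 0.00109). The 6 genes that were not lower, named after their values were seen, were Gm37608, Gm43846, the mitochondrial leucyl-tRNA synthetase gene Lars2, the ribosomal protein genes Rpl13 and Rpl7a, and mt-Atp8. Among the named sequences, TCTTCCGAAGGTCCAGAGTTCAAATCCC had 1 read against 11828 in wild type, a ratio of 1.29e-04 (1.81e-05 to 9.14e-04). The Hist1h3h sequence TTCAAGACCGACCTGCGCTTCCAGAGC had 0 against 1595, at least 349-fold lower when 0 is set to 3 counts in the Mili knockout library.

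The MILI immunoprecipitate was rich in piRNA-like reads and poor in every small RNA class of other kinds. The piRNA-like share was 1.83-fold higher than in untreated wild type (1.83 to 1.83), and its reads in the sense of protein-coding genes 2.20-fold higher (2.19 to 2.20), at 50.1% of the library. The MILI-bound set was 2.15-fold higher (2.15 to 2.16), a value that is partly set by its definition from the same library. microRNAs were 22.5-fold lower (22.4 to 22.6), mitochondrial fragments 67.4-fold (66.2 to 68.7), snRNA and snoRNA fragments 5.04-fold (5.01 to 5.07), rRNA fragments 3.57-fold (3.55 to 3.59) and tRNA fragments 1.64-fold lower (1.63 to 1.64), and Mir5099-locus reads 963-fold lower (922 to 1006). The MILI-bound set held 16.2% of untreated wild type, 25.1% with NaIO4, 17.5% and 5.76% of the Hen1 knockout without and with NaIO4, and 3.50% of the Mili knockout, where it was 4.63-fold lower than in wild type (4.61 to 4.65). Among the 11488 sequences of the set with at least 100 reads, 634 lay within 4 edits of the sense strand of SINE B2 and held 19.9% of the reads of these sequences in the immunoprecipitate, and 0 matched its antisense strand. For SINE B1 the sense strand had 97 sequences with 0.832% of the reads and the antisense strand 2. SINE-matching sequences were 1.59-fold higher with NaIO4 in wild type (1.58 to 1.61), 3.82-fold lower in the Hen1 knockout (3.73 to 3.92) and 350-fold lower in the Mili knockout (291 to 419).

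piRNAs made by reciprocal cleavage of both strands, the ping-pong cycle, overlap by 10 nt at their 5′ ends. On transcripts, 27.7% of all pairs of opposite piRNA-like reads that overlapped by 1 to 20 nt overlapped by 10 nt in untreated wild type, and the z-score of that overlap was 16.5. The share and z-score were 24.0% and 11.1 in wild type with NaIO4, 33.3% and 29.4 in the untreated Hen1 knockout, 26.4% and 9.502 with NaIO4, and 24.0% and 15.5 in the immunoprecipitate. In the Mili knockout 4.64% of pairs overlapped by 10 nt, the z-score was -0.18 and the most common overlap was 9 nt. That z-score was 0.559 with distinct sequences counted once, and for the untreated Hen1 knockout it was 8.9997 under that setting and 9.66 with 1-gene reads, so the order of the other 5 libraries depended on the setting. The z-score compares 10 nt with the other 19 overlaps of the same library and is a description, not a test.

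**Figure D4:**
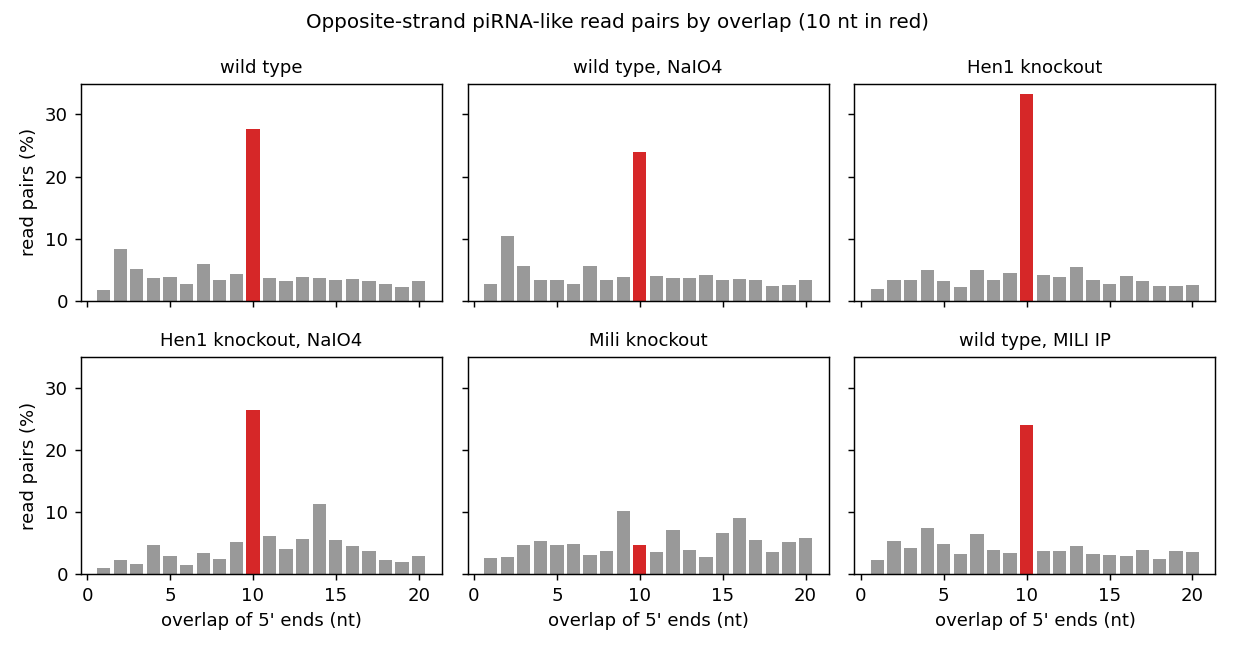
Share of opposite-strand pairs of piRNA-like reads (%) at each overlap of their 5′ ends, from 1 to 20 nt, by library. The overlap of 10 nt held 27.7% of pairs in untreated wild type and 33.3% in the untreated Hen1 knockout, against 4.64% in the Mili knockout.

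Within microRNA reads, the Hen1 knockout had more of the let-7, miR-290 and fibroblast microRNAs than wild type. The wild type was led by the X-linked germ line microRNAs Mir741-3p, 16.6% of microRNA reads, Mir871-3p, 15.2%, and Mir470-5p, 6.23%, followed by Mir183-5p at 5.37%. All 9 measured arms of the let-7 family, regulators of differentiation, were higher, among them Mirlet7a-5p 2.39-fold (2.27 to 2.53) and Mirlet7i-5p 2.60-fold (2.44 to 2.77), with a list median of 1.15 on the log2 scale at the 96.7th percentile of 10000 random lists of matched level. The fibroblast list, which marks the feeders, had 8 of 9 arms higher, with Mir199a-5p 2.79-fold (2.68 to 2.89) and Mir10b-5p 2.32-fold (2.24 to 2.41) and a median of 1.22 (98.5th percentile). All 8 arms of the miR-290 and miR-302 clusters, typical of pluripotent cells, were higher, with Mir292-3p 2.90-fold (2.62 to 3.20) and a median of 0.82 (92.9th percentile), as were both meiotic arms, Mir34c-5p 2.62-fold (2.42 to 2.83) and Mir34b-3p 2.04-fold (1.60 to 2.61), with a median of 1.21 (90.0th percentile). The list of undifferentiated spermatogonia had 5 of 12 arms higher and a median of -0.23 (0.41th percentile, or -0.05 and the 10.8th with arms of at least 50 reads), with Mir183-5p at 0.615 (0.606 to 0.623), Mir96-5p at 0.573 (0.561 to 0.585) and Mir182-5p at 0.756 (0.737 to 0.775), against Mir21a-5p at 2.23 (2.17 to 2.30). The proliferation-linked miR-17 and miR-106b clusters had 4 of 13 arms higher and a median of -0.12 (5.51th percentile), with Mir92-3p at 0.924 (0.902 to 0.946) and Mir20a-5p at 0.823 (0.779 to 0.869). Single arms stood for the blood list, Mir486-5p at 1.12 (0.969 to 1.29; 39.2th percentile), and the endothelial list, Mir126a-3p at 0.638 (0.533 to 0.765; 4.93th percentile), the list of mirtrons and other microRNAs made without Drosha had a median of 0.12 over 2 arms (43.4th percentile), and the muscle list had 0 measured arms here and in the other comparisons.

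By the rule of size, 60 of 277 microRNA arms with at least 200 reads in both libraries together were at least 2-fold higher in the Hen1 knockout and 3 at least 2-fold lower, or 96 and 19 with at least 50 reads. The highest ratios were those of Gm24810-3p, 10.4-fold (8.45 to 12.7), n-TSaga9-5p, 6.99-fold (5.84 to 8.36), Mir5121-3p, 5.23-fold (3.81 to 7.17), Gm24245-5p, Gm22463-3p, Gm22419-5p and Gm26318-3p, 4.42-fold to 4.80-fold, and Mir199b-5p, 4.32-fold (3.64 to 5.11). The lowest were Mir141-3p, 2.57-fold lower (2.05 to 3.22), Mir10a-5p, 2.34-fold lower (2.28 to 2.40), and Mir93-3p, 2.31-fold lower (1.71 to 3.11), then Mir485-3p, Mir182-3p, Mir26b-5p, Mir96-3p and Mir381-3p, 1.82-fold to 1.91-fold lower. Scaling to all reads of 18 to 35 nt multiplies each ratio by 0.383, which gave 3 higher and 159 lower and put the medians of all 9 measured lists below 0, so these directions are relative to other microRNAs alone.

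In the Mili knockout the let-7, meiotic and fibroblast lists had the highest medians relative to other microRNAs. All 10 let-7 arms were higher, with Mirlet7a-5p 1.63-fold (1.55 to 1.71) and a median of 0.74 (100th percentile), and 8 of 9 fibroblast arms, with Mir199a-5p 1.92-fold (1.85 to 1.99) and a median of 0.62 (99.8th percentile). All 3 meiotic arms were higher, with Mir34c-5p 1.61-fold (1.49 to 1.73) and a median of 0.68 (96.8th percentile). The miR-290 and miR-302 clusters had 2 of 9 arms higher and a median of -0.30 (8.71th percentile), with Mir292-5p at 0.814 (0.757 to 0.875). The miR-17 and miR-106b clusters had 2 of 14 higher and a median of -0.13 (12.8th percentile), and undifferentiated spermatogonia 5 of 12 and a median of -0.13 (10.3th percentile), with Mir183-5p at 0.755 (0.747 to 0.763). The blood, endothelial and mirtron lists had medians of -0.35 (21.8th percentile), 0.08 (64.6th percentile) and 0.28 (80.0th percentile). Of 283 arms, 2 were at least 2-fold higher, Mir181a-5p, 2.35-fold (1.97 to 2.81), and Mir214-3p, 2.05-fold (1.68 to 2.50), followed by Mir365-3p, Mir193b-3p, Mir199a-5p, Mir34b-3p, Mir222-3p and Mir351-5p, 1.86-fold to 1.99-fold higher. At least 2-fold lower were 23, or 13 at 20 to 24 nt alone and 57 with at least 50 reads, and 17 of the 23 were entries without a Mir name. They were led by Gm22463-5p, 120-fold (65.2 to 220), Gm25240-5p, 99.01-fold (70.1 to 140), Gm22355-5p, 73.8-fold (55.7 to 97.7), Gm22002-5p, 52.1-fold (31.5 to 86.1), Gm27512-5p, 47.2-fold (37.3 to 59.6), Gm26318-3p, Gm25190-3p and Gm22355-3p, 30.7-fold to 43.6-fold. Scaling to all reads multiplies each ratio by 1.77, which gave 93 higher and 13 lower and put the medians of all 9 measured lists above 0.

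With NaIO4, microRNAs were lower as a class, with a wide spread between arms. In wild type 49 of 247 arms were at least 2-fold higher relative to other microRNAs and 24 lower, and in the Hen1 knockout 22 and 21 of 216; per all reads the counts were 4 and 207, and 10 and 179, and with at least 50 reads 86 and 44, and 41 and 48. At 20 to 24 nt alone 25 were higher in wild type. The factors between the scalings were 0.0772 and 0.351, and per all reads the medians of all 9 and all 8 measured lists lay below 0. Mir194-5p had the highest ratio in both genotypes, 41.2-fold in wild type (34.0 to 49.9) and 41.2-fold in the knockout (33.9 to 50.1), followed by Gm22002-5p, 29.1-fold (26.7 to 31.7) and 28.8-fold (26.01 to 32.0). Next in wild type came Gm22752-3p, 28.3-fold (21.8 to 36.6), Mir546-3p, 26.4-fold (21.1 to 33.1), Gm27907-5p, 25.4-fold (20.5 to 31.5), Gm22419-5p, Gm22463-5p and Gm24105-3p, 19.7-fold to 22.8-fold, and in the knockout Mir6236-5p, 15.3-fold (13.0 to 17.9), Gm22463-3p, Gm47301-3p, Gm24245-3p, Mir6240-3p and Gm24049-3p, 9.21-fold to 14.6-fold. Mir880-3p, one of the X-linked germ line microRNAs, was 5.51-fold lower in wild type (5.19 to 5.84) and 5.67-fold lower in the knockout (5.10 to 6.31). The other lowest ratios rested on few reads with NaIO4, such as Mir27a-5p at 0.10004 (0.0288 to 0.348), Mir543-3p, Mir370-3p, Mir295-5p, Mir423-5p, Mir296-3p and Mir409-3p in wild type and Mir151-3p at 0.0988 (0.0285 to 0.343), Mir346-5p, Mir181c-3p, Mir1195-5p, Mir296-5p, Mir25-5p and Mir423-5p in the knockout.

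With NaIO4, let-7, miR-17 and other fixed lists ranged widely among random lists, with none above the 75th percentile in the main setting and up to the 92.4th, for endothelium in wild type, at 20 to 24 nt. The mirtron list was lowest in the knockout, with a median of -0.92 in wild type (4.22th percentile), where the single blood arm Mir486-5p lay lower still at -1.73 (2.29th percentile), and -1.01 in the knockout (3.97th percentile), with Mir320-3p at 0.526 (0.414 to 0.667) and 0.561 (0.418 to 0.752) and Mir484-5p at 0.533 (0.402 to 0.708) and 0.437 (0.263 to 0.725). For let-7 the medians were -0.21 (22.6th percentile) in wild type and -0.06 (40.3th) in the knockout, for the miR-17 and miR-106b clusters -0.01 (55.4th) and -0.22 (14.8th), and for the miR-290 and miR-302 clusters -0.03 (49.0th) and 0.03 (70.2th). Undifferentiated spermatogonia had -0.40 (13.4th percentile) and -0.28 (10.9th), fibroblasts -0.06 (42.2th) and 0.04 (58.3th), and the meiotic arm Mir34c-5p 0.43 (60.1th) and -0.67 (7.78th). The blood arm was at -0.37 (37.3th) in the knockout, and the endothelial arm Mir126a-3p at 1.09 (74.7th) in wild type, with 0 measured arms in the knockout.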

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

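The NaIO4 ratio lay on opposite sides of 1 in the 2 genotypes for 3 classes, a difference between groups that was not tested, since each group had 1 library. The knockout ratio over the wild type ratio was 0.229 for piRNA-like reads (1.61 in wild type and 0.369 in the knockout), 3.03 for snRNA and snoRNA fragments (0.393 and 1.19) and 1.69 for unclassed reads of other lengths (0.848 and 1.43). The last 2 depended on the total, since per Mir5099-locus read they were 0.891 (0.344 and 0.307) and 0.497 (0.743 and 0.369), and per microRNA read 0.666 and 0.371, with both genotypes on the same side of 1. For piRNA-like reads the knockout ratio was 1.05 per microRNA read, against 20.9 in wild type. For piRNA-like reads the design gives a biological explanation, the missing 2′-O-methylation without Hen1, and the low knockout ratio is in line with it in these libraries.

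Structural RNA fragments with higher shares after NaIO4 in both genotypes could come from reads primed within the RNA itself, and these tests were chosen after the pattern was seen except that on piRNA-like sequences. At 24 structural RNA ends followed by at least 5 of 6 bases like the start of the 3′ adapter, the median knockout ratio was 11.8 times that at 615 ends with at most 2 such bases, but rearranged hexamers gave a median of 4.78 and up to 9.43, and only 9 of them had ends enough, too few to place the value. Of the 7 ends of structural RNAs and microRNA entries at least 2-fold higher in both genotypes, 3 (42.9%) had adapter-like sequence over 12 bases, against 3.83% of 1123 others and at most 14.3% for 200 shuffled adapters, a difference that goes with this explanation but rests on 7 ends, with the same position of 5S rRNA copies counted 2 times and the microRNA entry Gm22002 as the third, and on an adapter sequence assumed from the Illumina protocol, while 0% of 47 piRNA-like sequences of 1 gene at least 2-fold higher in the knockout had it (upper bound 7.55%) against 1.59% of the others, too few to tell. Across 12 bases the median ratios were 0.0949 in wild type and 0.358 in the knockout at 391 ends with at most 2 matches and 0.524 and 1.91 at 44 ends with 7 or 8, and the Mir5099-locus RNA has 8 after its end, so its own higher share, and with it the scaling per Mir5099-locus read, may come from priming. That explanation, higher shares of what is left when other RNAs are lost, and a real end modification that does not need Hen1 stay open, and no biological explanation was tested.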

How the results depend on the processing

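No paired analysis was possible because each group had 1 library, and every value below is a description. Of 243 values under alternative settings for 95 results, 93 stayed within the counting interval, within 1.5 times for counts or, for list percentiles, within 10 points, 148 moved and 2 reversed. Of the 5 piRNA-like ratios, 4 kept their direction under every setting run, and that of NaIO4 in the Hen1 knockout reversed per microRNA read, to 1.05. They ranged from 1.15 to 20.9 for NaIO4 in wild type, from 0.0953 to 1.05 in the Hen1 knockout, from 0.0504 to 0.624 for the ratio of these ratios, from 1.11 to 3.76 for the untreated Hen1 knockout against wild type and from 0.0358 to 0.415 for the Mili knockout against wild type. The cause was not tested for any value that moved, beyond what the setting itself fixes. Settings chosen in advance that use genome-matched reads as the total, or reads with 1 place in the genome, were not run, since no genome sequence was in the reference. Intervals of deep libraries are narrow, so small moves are listed, while sequences and microRNAs with few reads limit every count by size.

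Ratios below stand in the order NaIO4 in wild type, NaIO4 in the Hen1 knockout, the ratio of these, the untreated Hen1 knockout and the Mili knockout. At 26 to 28 nt they were 1.71, 0.353, 0.206, 1.72 and 0.183. Without the 10 most abundant sequences they were 1.56, 0.557, 0.358, 1.39 and 0.271. With distinct sequences counted once they were 1.15, 0.718, 0.624, 1.11 and 0.415, and with up to 1 mismatch to small RNAs 1.64, 0.348, 0.212, 1.46 and 0.193. Of transcript-matched reads they were 1.80, 0.267, 0.148, 1.40 and 0.0358, and per Mir5099-locus read 1.41, 0.0953, 0.0674, 1.296 and 0.125. Without sequences of fewer than 2 reads the first 4 were 1.65, 0.337, 0.204 and 1.44, and per microRNA read all 5 were 20.9, 1.05, 0.0504, 3.76 and 0.131.

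Shares below stand in the order wild type, wild type with NaIO4, Hen1 knockout, Hen1 knockout with NaIO4, Mili knockout and immunoprecipitate. Reads of 25 to 31 nt made up 55.4%, 78.7%, 70.6%, 47.2%, 26.8% and 77.3% without the 10 most abundant sequences, and 72.0%, 81.7%, 79.2%, 58.4%, 35.3% and 73.7% with distinct sequences counted once. T stood first in 74.7%, 78.5%, 78.3%, 69.9%, 27.4% and 77.04% with distinct sequences, and in 73.2%, 80.3%, 80.2%, 63.0%, 36.1% and 85.7% at 26 to 28 nt. With up to 1 mismatch the piRNA-like shares were 37.8%, 62.0%, 55.3%, 19.2%, 7.30% and 71.1%. That setting gave microRNA shares of 21.5%, 1.85%, 8.44%, 3.10%, 38.0% and 1.16%, tRNA shares of 6.65%, 5.04%, 7.99%, 5.54%, 9.32% and 5.73%, and rRNA shares of 3.97%, 6.97%, 3.21%, 18.8%, 7.61% and 1.12%. With MILI-bound limits of 2 and 100 reads, the set was 2.58-fold and 2.24-fold higher in the immunoprecipitate and at 0.209 and 0.256 of wild type in the Mili knockout.

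Sequences at least 2-fold higher with NaIO4 in wild type and in the knockout numbered 13691 and 2032 per microRNA read, 2126 and 57 per Mir5099-locus read, 307 and 97 with at least 50 reads, and 223 and 188 by a 4-fold rule. The median 3′ end difference was -0.58 nt at 5′ ends with at least 200 reads and -0.79 nt with at least 20. The z-scores of the 10 nt overlap with distinct sequences were 10.4, 8.73, 8.9997, 9.11, 0.559 and 6.87, of which that of the Mili knockout reversed from -0.18. With reads of 1 gene they were 13.1, 15.3, 9.66, 8.78, -0.77 and 8.41.

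microRNAs at least 2-fold higher and lower per all reads numbered 3 and 159 in the Hen1 knockout, 93 and 13 in the Mili knockout, 4 and 207 with NaIO4 in wild type and 10 and 179 with NaIO4 in the Hen1 knockout. With 50 reads or more they were 96 and 19, 13 and 57, 86 and 44, and 41 and 48. At 20 to 24 nt, 13 were lower in the Mili knockout and 25 higher with NaIO4 in wild type. The factor between scalings changed the sign of list medians as given with the microRNAs.

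Of 105 percentiles of lists under alternatives, 86 stayed within 10 points. With 50 reads, those that moved were 10.8 for undifferentiated spermatogonia and 17.04 for endothelium in the Hen1 knockout and 45.2 for endothelium in the Mili knockout. With NaIO4 in wild type they were 37.6 for the miR-17 list, 33.0 for the miR-290 list, 71.2 for the meiotic list and 10.9 for fibroblasts, and in the Hen1 knockout 28.8 and 56.8 for the miR-17 and miR-290 lists. At 20 to 24 nt with NaIO4 in wild type, let-7 was at 43.4, the miR-17 list at 75.4, the miR-290 list at 76.0, the meiotic list at 79.6, fibroblasts at 59.1 and endothelium at 92.4, and in the Hen1 knockout undifferentiated spermatogonia at 31.1 and fibroblasts at 82.8. Per all reads with NaIO4 in wild type the meiotic list was at 82.5 and fibroblasts at 28.1.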

Other observations

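Among tRNA fragments, the 5′ part of tRNA-Asp-GTC was enriched with MILI and with NaIO4 but was lost less than gene-derived piRNAs in the Mili knockout. It was 4.39-fold higher in the MILI immunoprecipitate than in untreated wild type (4.32 to 4.45), 1.44-fold higher with NaIO4 in wild type (1.42 to 1.47), at 0.290 with NaIO4 in the Hen1 knockout (0.278 to 0.303) and at 0.529 in the Mili knockout, where piRNA-like reads in the sense of protein-coding genes were at 0.0334. The 5′ part of tRNA-Gln-CTG had NaIO4 ratios of 1.19 and 0.233 in the 2 genotypes and a ratio of 0.397 in the Mili knockout. The 5′ part of tRNA-Lys-TTT was lost with NaIO4 in both genotypes, at 0.0715 (0.0686 to 0.0745) and 0.134, and was at 0.0609 in the immunoprecipitate. The 5′ part of tRNA-Gly-GCC, a common stress-linked fragment, was at 0.346 and 0.409 with NaIO4, 2.05-fold higher in the Mili knockout and 1.89-fold higher in the Hen1 knockout.

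Entries annotated as microRNA but without a Mir name, such as Gm22463 and Gm22002, differed from named microRNAs, a division made after their values were seen. In the Mili knockout 17 of 26 such arms were at least 2-fold lower relative to all microRNAs, against 6 of 257 named Mir, and their share of all reads was at 0.591 of wild type, and with NaIO4 in wild type 38 of 40 were at least 2-fold higher relative to all microRNAs, against 11 of 207. Their reads had a mean length of 24.4 nt in wild type, against 22.4 nt, and their share was at 0.875 with NaIO4 in wild type, against 0.0609 for named ones. With NaIO4 in the Hen1 knockout their share was at 1.06, against 0.318, so it was not lower there. In the immunoprecipitate it was at 0.748 of untreated wild type, against 0.0301, so these entries as a group were not enriched with MILI. Single arms among those lowest in the Mili knockout differed. Gm26318-3p had 10341 of 25240941 reads in the immunoprecipitate and 1442 of 7322408 in untreated wild type. Gm22355-3p had 8832 and 1172, so both had a higher share with MILI. Gm22355-5p had 8161 and 3138, a lower share with MILI. In the untreated Hen1 knockout 22 of 39 such arms were at least 2-fold higher relative to all microRNAs, against 38 of 238, while their share of all reads was at 0.831 of wild type. Of 8873 MILI-bound sequences with at least 20 reads in wild type, 7954 (89.6%) had 0 reads in the Mili knockout, and the 422 that were not lower held 89.4% of the reads left in the set. In the Mili knockout, reads that share a 5′ end with MILI-bound reads were 22 nt long in 18.3%, against 7.68% in wild type. That share was 23.0% in the Hen1 knockout with NaIO4 and 2.66% without, so a high value was not particular to the Mili knockout.

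The 3′ ends of MILI-bound reads were shorter and more often tailed in the untreated Hen1 knockout; of the tests here, that on microRNAs was written before the result was seen and that on 5′ ends after. A library-wide difference in adapter trimming would shorten microRNAs too, and their median difference of 0.0102 nt over 348 5′ ends, with a T tail ratio of 1.08, argued against it. Sampling of other 5′ ends was ruled out by the construction of the comparison within 5′ ends (median -0.72 nt), which is no separate check. Missing 2′-O-methylation, which leaves 3′ ends open to trimming and tailing, may explain the pattern and is the explanation the design gives, but with 1 library it cannot be separated from a difference between colonies.

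The microRNA share was lower and the piRNA-like share higher in the untreated Hen1 knockout; the test on feeders was written before its result was seen and that on abundant sequences after. Fewer feeder cells would lower fibroblast microRNAs among microRNAs, and their list median of 1.22 on the log2 scale argued against it. That the 10 most abundant sequences alone gave it was argued against by a piRNA-like ratio of 1.39 without them. With distinct sequences counted once the ratio was 1.11, so a part carried by a wider set of abundant sequences was not excluded. A difference in cell state between single colonies, in library preparation, or an effect of Hen1 loss could each give this pattern, and these stay open.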
